A study of Mus musculus with 6 samples.

How the data were processed

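Genomic DNA from male germ cells of mice was extracted with the DNeasy Blood & Tissue Kit and made into libraries with the Zymo-Seq RRBS Library Kit, per the labels. There are 3 Control and 3 CSDS libraries, grouped by their titles. Reads were trimmed with Trim Galore 0.5.0 and aligned and called with Bismark 0.20.0 against GRCm38, per the submitters' processing notes. Each deposited table gives, per the file headers, the chromosome, position and strand of a cytosine in a CpG, its coverage as a count of reads, and the percent of those reads that show C (methylated) or T (unmethylated). The deposited percent values times the coverage count gave whole numbers at every position to within 1e-06, so methylated and unmethylated counts were taken from them. No position with a coverage under 10 is listed. Handling of duplicates, base quality filters and the bisulfite conversion rate are not stated in the labels or headers. Reads carry no molecular identifiers that the labels name, so coverage counts reads and not independent molecules, and counting precision is a lower bound on the error.

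Cytosines listed in all 6 libraries with a coverage of at least 10 in each were used, without those in the top 0.1% of coverage of any library. Of 3348459 cytosines listed in at least 1 library, 2210988 (66.0%) were listed in all and 4668 were left out by the cap. The 2 strands of a CpG were kept apart. Coordinates are 1-based on GRCm38. The gene annotation, of assembly GRCm38.p6, gives each gene's chromosome, start and end but no strand and no exons. Promoters, which the design had fixed as 1 kb either side of a transcription start, were therefore replaced by windows of 1 kb either side of a gene end, for protein-coding and listed genes, at the end with more covered cytosines. At that end 84.3% of windows were under 20% methylated, with a median of 10.6%, against a median of 88.9% at the other end. Exons, introns and untranslated regions could not be separated, and contexts were gene ends, gene interiors, intergenic DNA, chromosome classes and CpG density (CpG-dense, at least 20 listed cytosines within 100 bp; CpG-poor, at most 6). Tiles were 500 bp wide with at least 3 cytosines, and windows also held at least 3. Imprint control regions were placed by their approximate known positions in GRCm38, written down before their values were seen, so their bounds are not exact.

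Global, context and imprint levels are means over cytosines per library, each cytosine weighted equally, and were compared by exact two-sided permutation tests of the difference of group means, with Benjamini-Hochberg adjustment within contexts and within regions. For cytosines, tiles and windows, methylated and unmethylated counts were fitted by a binomial logistic model with group as its term. The quasi-binomial dispersion per feature was moderated by the method of limma's squeezeVar and held at 1 or above, followed by an F test and Benjamini-Hochberg adjustment. Features were called at an adjusted p under 0.05 with a difference of group means of at least 10 points. Features at 0 or at 100% in all libraries were not tested. Gene lists (14, fixed with the rest of the design before the data were examined) were counted over all windows and over the list alone. Lists with at least 4 measured members (12) were tested by limma's camera, with a preset correlation of 0.01, on log2 of methylated over unmethylated reads with a pseudocount of 1. The lists are maternally and paternally imprinted genes, germline-specific genes, spermatogenic stages, the stress axis, neuronal genes, metabolism, DNA methylation and piRNA machinery, stress-responsive chromatin factors, Sertoli, Leydig and immune markers, Hox genes and clustered protocadherins. Of the listed genes, 2 are not in the gene table.

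Genes named in the text follow a rule of the same design. It takes called features of largest difference (up to 15 gene ends, 10 tiles and 5 cytosines each way) and, where fewer than 10 of a kind are called, the 10 each way of smallest unadjusted p among features whose groups do not overlap. From each list it takes members called over the list alone and up to 4 of largest absolute difference, and it takes all imprint regions with data. No feature was called, so those named here come from the rest of the rule, and 1 listed gene that it picks is not reported here. Hox genes that pass over the list alone without reaching 10 points are named outside it, chosen after their values were seen.

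Non-conversion was examined after the data were seen. The share read as C was taken as the median over all 27 mitochondrial CpG cytosines, with the 3 that read above 90% in every library kept in, and as the median over the windows of 28 broadly expressed genes (26 measured), a list written after the mitochondrial values and before its own were seen. Levels were corrected by dividing the unmethylated share by 1 minus that share, so corrected levels can fall below 0. In tests on corrected counts, values were rounded and held at 0. A second approach added a term for CSDS replicates 2 and 3 against the other libraries. These libraries belong to 1 group, so with that term the group difference rests on CSDS replicate 1 alone against the Control libraries.

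Alternatives fixed in advance were Fisher's exact test on summed counts, an unmoderated dispersion, edgeR's negative binomial model with a library coefficient, limma on logit values, the replicate number as a block, no difference minimum or one of 25 points, a coverage minimum of 20, no coverage cap, tiles of 200 and 1000 bp, at least 5 cytosines per tile, both cytosines of a CpG merged, read-weighted levels, each library's own cytosines, camera with an estimated correlation, fry, and each replicate left out in turn. Added after the data were seen were the conversion term, the corrections, the other gene end, windows of 2 kb, CSDS replicate 1 alone against Control, the removal of CpGs whose strands differ, and corrected levels with each replicate left out in turn. A coverage minimum of 5 and a window from 2 kb upstream to 500 bp downstream of the start could not be applied, for lack of cytosines under 10 reads and of strand.

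The quasi-binomial test with and without the conversion term, limma on logit values and edgeR were tried on simulated data drawn from the real features. Fisher's exact test, the unmoderated dispersion, and limma and edgeR with the conversion term were not. The simulated data held 200 changed features, 50 at each of 10, 20, 30 and 40 points. For gene-end windows of CSDS against Control (14690) the quasi-binomial test called 26%, 74%, 88% and 94% of them, with 2 unchanged windows. For 500-bp tiles (162809) it called 8%, 60%, 84% and 96%, with 5 unchanged, and for single cytosines (200000 drawn) 2%, 24%, 54% and 82%, with 11 unchanged. With the conversion term the quasi-binomial test called 18%, 62%, 74% and 82% of changed windows, 2%, 22%, 64% and 80% of tiles and 0% of cytosines at every size, so its count of 0 there says nothing. edgeR called 35, 109 and 21 unchanged features there, and limma 8, 2 and 0. For the gene lists (14690 windows, 20 draws), camera recovered a shifted list in 20 draws and fry in 18, and 4 of 220 unshifted lists passed with each. The simulated data hold no difference in conversion between libraries. Their changes were gains at features under 50% in Control and losses at the others. Most windows were under 20%, so the rates for windows are mostly those of gains, while most real differences were losses.

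Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and the data.table package, version 1.17.8.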

Results

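DNA methylation was profiled in male germ cells of mice by reduced representation bisulfite sequencing, a method that reads cytosines near fixed restriction sites and therefore favours CpG-rich DNA. The 6 libraries form 2 groups of 3, Control and CSDS, the second for chronic social defeat stress, in which an animal meets a dominant aggressor again and again. Each library listed between 2420308 and 3156788 cytosines in CpGs, on either strand, each read at least 10 times. Median coverage ran from 44 to 50 reads per cytosine. In all, 2210988 cytosines were listed in all 6 libraries, and 2206320 of them, those below a coverage cap, entered the comparisons. Across these cytosines the correlation between any 2 libraries was between 0.967 and 0.982. The labels do not say that the replicates are separate animals, so the p-values below measure only the spread between these samples.

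As deposited, the share of reads that show C in germ cell DNA was lower in every CSDS library than in every Control library, and after a correction for non-conversion by the mitochondrial share the groups overlapped through Control replicate 3 alone. The mean over all cytosines as deposited was 43.2% ± 0.141 (SD, n = 3) in Control and 40.6% ± 1.71 (SD, n = 3) in CSDS. The CSDS libraries stood at 42.6%, 39.5% and 39.7% for replicates 1, 2 and 3, and the lowest Control library at 43.1%. The difference was −2.60 points, more than the Control spread, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give, so no such comparison here can reach 0.05. With reads summed over cytosines, so that deep cytosines weigh more, the difference was −4.43 points. The question this addresses is whether social defeat alters the methylation of the germ line.

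Loci taken to be unmethylated, where reads that show C may be unconverted cytosine, read as C less often in CSDS replicates 2 and 3 than in the other 4 libraries, while CSDS replicate 1 lay near Control. At 27 CpG cytosines of the mitochondrial genome, whose DNA is largely unmethylated, 22 were under 20% in every library, 3 were above 90% in every library and 2 lay between. The median read as C over the 27 was 8.90%, 8.84% and 10.04% in the 3 Control libraries and 8.50%, 4.41% and 4.53% in CSDS replicates 1, 2 and 3. At 26 gene-end windows of broadly expressed genes such as Actb and Gapdh it was 11.999%, 12.3% and 11.9% against 11.2%, 6.54% and 7.43%. After each library was corrected for its mitochondrial share, the global level was 37.4% ± 0.611 (SD, n = 3) in Control and 36.95% ± 0.265 (SD, n = 3) in CSDS, a difference of −0.462 points (exact permutation p = 0.4). It was −0.239 without Control replicate 2, and −0.810 with groups apart without Control replicate 3. That library had the highest mitochondrial share but the lowest housekeeping share of the Control libraries. At cytosines under 20% on average the mitochondrial correction put it at −1.78%, against −0.390% and −0.0618% in Control replicates 1 and 2. With the housekeeping share in place of the mitochondrial share the levels were 35.4% ± 0.06005 and 35.2% ± 0.231 (SD, n = 3 each). That difference, −0.236 points (−0.103 without CSDS replicate 3), was over the Control spread and the groups did not overlap (exact permutation p = 0.1). In each library the housekeeping share lay above the mean at cytosines under 20% on average as deposited (8.59% in Control, 5.33% in CSDS). That correction therefore takes away more than these cytosines hold, so the share is not a non-conversion rate common to all cytosines. CSDS replicate 1, with shares near those of Control but below each Control library, differed from the Control mean by −0.633 points as deposited. After correction it differed by −0.167 points with the mitochondrial share and by −0.0928 with the housekeeping share.

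Sites near gene ends and in CpG-dense DNA, which are mostly unmethylated, showed the largest differences between the groups as deposited with each cytosine weighted equally, and CpG-poor DNA the smallest. Within 1 kb of a gene end, 923389 cytosines averaged 16.5% ± 0.222 in Control and 13.1% ± 2.36 in CSDS (SD, n = 3 each), a difference of −3.39 points. CpG-dense cytosines averaged 13.8% ± 0.202 and 10.5% ± 2.34, a difference of −3.32 points. Gene interiors differed by −2.13 points (57.3% against 55.2%) and intergenic DNA by −1.88 points (69.7% against 67.8%). CpG-poor cytosines, at 82.1% ± 0.205 and 80.7% ± 0.662, differed by −1.38 points. The X chromosome differed by −2.51 points and the Y chromosome by −2.09 points (−1.34 without CSDS replicate 3). With reads summed over cytosines the differences were −4.23 points in gene interiors, −3.48 in intergenic DNA and −2.80 in CpG-poor DNA. Each of the 8 contexts had an exact permutation p of 0.1, and 0.1 after Benjamini-Hochberg adjustment. After the mitochondrial correction the larger differences lay in the methylated contexts: CpG-dense cytosines differed by −0.0362 points (−0.513 without Control replicate 3, +0.313 without Control replicate 2), cytosines near gene ends by −0.226 (−0.695 and +0.128 likewise), gene interiors by −0.534 (−0.805 without Control replicate 3), intergenic DNA by −0.768 and CpG-poor cytosines by −0.734. Of the contexts, only CpG-poor cytosines then kept the groups apart (exact permutation p = 0.1, 0.4 adjusted by Benjamini-Hochberg). CSDS replicate 1 differed there from the Control mean by −0.507 points. The housekeeping share is itself taken from gene ends, so with that correction a difference near 0 at gene ends (+0.118 points, groups overlapping, exact permutation p = 0.5) holds by construction. CpG-dense cytosines were at +0.325 points (+0.1796 without CSDS replicate 2) and CpG-poor cytosines at −0.680 points (exact permutation p = 0.1 each, 0.16 adjusted by Benjamini-Hochberg).

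**Figure D1:**
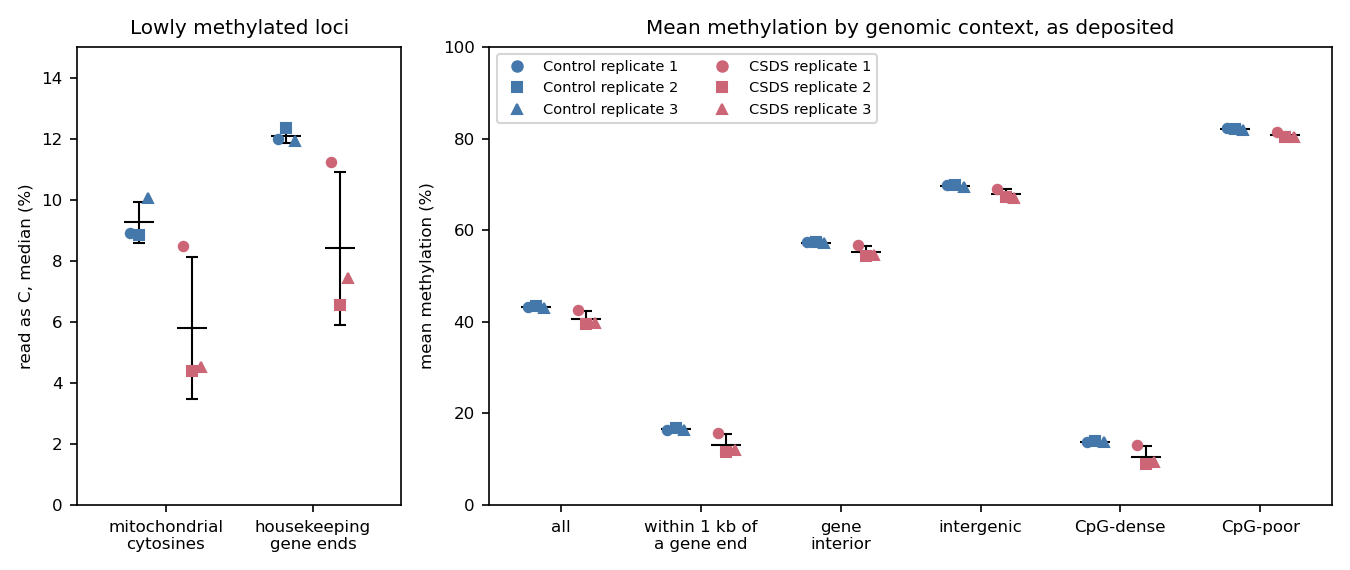
Left, the median percent of reads that show C at mitochondrial CpG cytosines and at housekeeping gene ends; right, mean methylation in percent by genomic context, with each symbol 1 library and bars the mean ± SD of 3 libraries per group. CSDS replicates 2 and 3 lie at 4.41% and 4.53% in the mitochondrial genome, below the other 4 libraries, and the same pair is lowest in every context.

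Germline imprints kept the pattern of male germ cells in both groups. These are regions methylated in only 1 parental lineage: maternally methylated regions are unmethylated in sperm, paternally methylated ones fully methylated. Of 21 regions, 20 had data (Mest had none). The 17 maternal regions had a median of 18.6% ± 0.949 in Control and 15.5% ± 3.19 in CSDS (SD, n = 3 each), a difference of −3.09 points (exact permutation p = 0.3; −4.93 without CSDS replicate 1, −2.05 without CSDS replicate 3). The 3 paternal regions, at H19, Meg3 and Rasgrf1, had medians of 96.6% ± 0.856 and 94.2% ± 0.787, a difference of −2.43 points (exact permutation p = 0.1). In 16 of the 17 maternal regions CSDS replicates 2 and 3, the libraries with the low mitochondrial share, both lay below the other 4 libraries. After the mitochondrial correction the maternal medians were 10.3% ± 1.58 and 10.3% ± 1.22, a difference of +0.0265 points that ran from −0.747 without Control replicate 3 to +0.829 without Control replicate 2. The paternal difference was −2.43 points after that correction. As deposited it was −1.08 points with a coverage minimum of 20 (exact permutation p = 0.4) and −1.45 with reads summed (exact permutation p = 0.3). If somatic DNA is taken to be 50% methylated at these regions, the corrected maternal medians would correspond to a somatic share of 20.6% ± 3.15 in Control and 20.7% ± 2.44 in CSDS. With the housekeeping correction it would be 14.9% ± 1.69 and 15.6% ± 2.47 (SD, n = 3 each). These shares exceed what the paternal regions allow under the same assumption, at 96.3% and 93.8% after the mitochondrial correction. CpG-dense cytosines in general kept 4.97% and 4.94% after it, so part of the maternal level need not come from somatic DNA. Left-out libraries moved the difference in share from −1.49 to +1.66 points with the mitochondrial correction and from −0.447 to +2.01 with the housekeeping correction, so its direction is not settled.

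Snrpn, the imprinted gene of the Prader-Willi region, showed the largest single difference among the imprints. Its control region on chromosome 7 (GRCm38, covered from 60004580 to 60005229, 23 cytosines, median 1714 reads per library) stood at 28.5% ± 3.68 in Control and 16.95% ± 3.35 in CSDS (SD, n = 3 each). The difference was −11.5 points (exact permutation p = 0.1), and −9.32 points after the mitochondrial correction. CSDS replicate 1 alone differed from the Control mean by −7.64 points. Inpp5f (−7.91 points, −4.99 corrected) and Nnat (−7.47, −4.54 corrected) came next, with CSDS replicate 1 at +0.522 and −2.43 points from the Control mean. Without it Inpp5f stood at −12.1 points, −8.15 corrected. H19 differed by −2.86 points, with 97.9% ± 1.17 in Control and 94.99% ± 0.613 in CSDS over 4 cytosines (median 191 reads per library; exact permutation p = 0.1). Meg3 differed by −1.33 points (−0.231 without CSDS replicate 2, −2.53 without CSDS replicate 3) and Rasgrf1 by −0.484, and Rasgrf1 turned to +0.182 points without Control replicate 2, to +0.280 without CSDS replicate 2 and to +0.0637 without CSDS replicate 3. Peg10 (+1.62 points) was the only region higher in CSDS, with +5.17 points after the mitochondrial correction (+3.21 without CSDS replicate 3), and without Control replicate 2 it stood at −0.0923. No region passed adjustment over the 20 regions, where the lowest adjusted p from the exact permutation tests was 0.40. Gnas exon 1A, Peg3, Kcnq1ot1 and Impact, lower in CSDS as deposited, were higher by 0.827, 0.918, 0.915 and 1.92 points after the mitochondrial correction. Without CSDS replicate 1 the corrected differences of Peg3 and Impact were −1.02 and −2.04 points, and that of Gnas exon 1A was +0.0952 without Control replicate 1 and that of Kcnq1ot1 +0.269 without Control replicate 3. As deposited, Peg3 was higher without CSDS replicate 2 (+0.975 points). Impact as deposited was higher without Control replicate 1 (+0.116), CSDS replicate 2 (+0.928) or CSDS replicate 3 (+1.19).

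**Figure D2:**
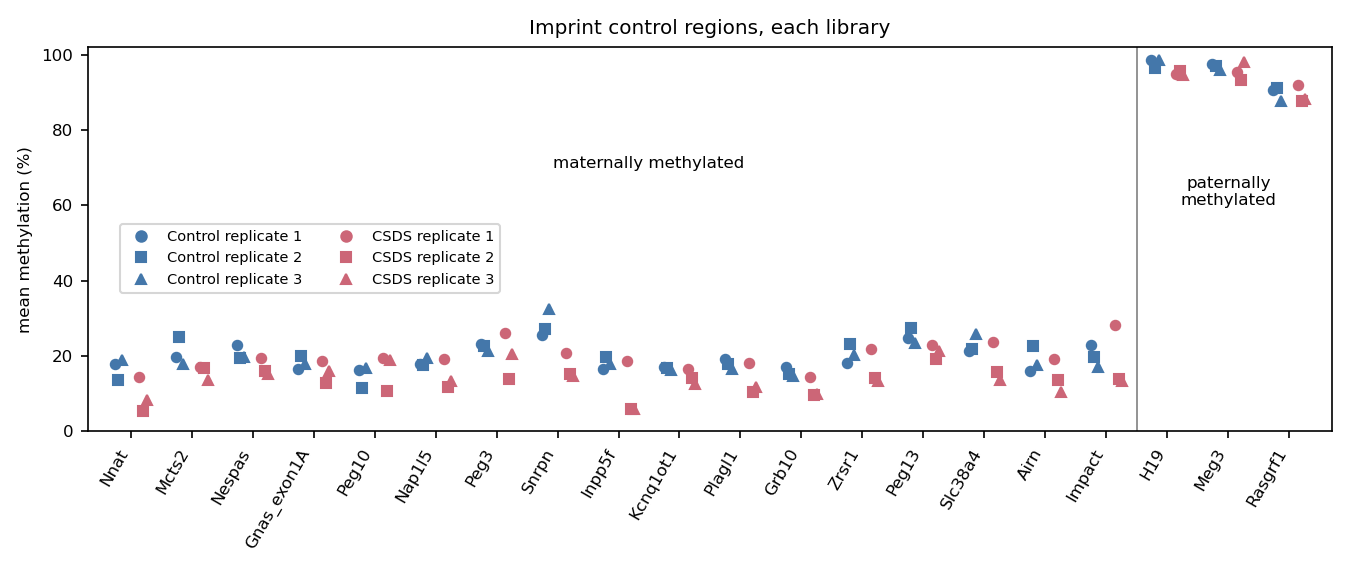
Mean methylation in percent of 20 imprint control regions, each symbol 1 library (3 Control, 3 CSDS), with maternally methylated regions left of the grey line and paternally methylated regions right of it. The maternal regions have group medians of 18.6% and 15.5%, the paternal ones 96.6% and 94.2%.

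Among gene ends of smallest unadjusted p with groups apart, Sox18, Ube2u and Ltc4s were lower in CSDS and Slc22a2 higher. None of them passed the test. Sox18 (gene 20672, chromosome 2 from 181669837 to 181671640) encodes a transcription factor of endothelial development. The window at its lower end, 43 cytosines with 2160 to 3790 reads per library, stood at 33.5% ± 3.59 in Control and 17.3% ± 3.51 in CSDS (SD, n = 3 each), a difference of −16.2 points. Ube2u (gene 381534, chromosome 4 from 100478867 to 100550145), a ubiquitin-conjugating enzyme, stood at 26.1% ± 3.62 and 9.10% ± 3.08, a difference of −16.95 points over 18 cytosines. Ltc4s, the leukotriene C4 synthase (gene 17001, chromosome 11), differed by −10.6 points (19.3% ± 3.53 against 8.62% ± 2.67). Slc22a2 (gene 20518, chromosome 17 from 12584189 to 12628489), an organic cation transporter, was at 42.6% ± 1.22 in Control and 53.0% ± 3.64 in CSDS, a difference of +10.4 points over 12 cytosines with 640 to 908 reads. After the mitochondrial correction the 4 differences were −14.5, −14.99, −8.03 and +13.3 points.

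The other lower windows of smallest unadjusted p with groups apart were those of Cdkn2d, an inhibitor of cyclin-dependent kinases (−7.33 points), the window shared by the peroxisome gene Pex3 and the tRNA deaminase gene Adat2 (−6.25), the ubiquitin ligase gene Wwp1 (−4.51), Dnajc14 (−5.50), Prkacb, a catalytic subunit of protein kinase A (−5.87), and 4833420G17Rik (−9.26). For Wwp1, Dnajc14, Prkacb and Pex3 the difference after the mitochondrial correction was −1.24, −2.28, −2.77 and −3.14 points. For Cdkn2d and 4833420G17Rik it was −4.60 and −6.52 points. The other higher windows were those of Ramp3 (+5.70 points), Eml1 (+4.04), the osteocalcin gene Bglap2 (+3.92), Gm46058 (+4.21), Alkbh6 (+5.83), Gm46320 (+8.87), Espnl (+4.14, +2.24 without Control replicate 3), AF067063 (+9.31) and Clec18a (+3.72). Their unadjusted p by the quasi-binomial F test ran from 0.0713 (Ramp3) to 0.169 (Clec18a). None was under 0.05, where 38.9% of all windows were. All of these higher windows except Alkbh6 stood above 80% in both groups, where unconverted cytosine would add little.

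**Figure D3:**
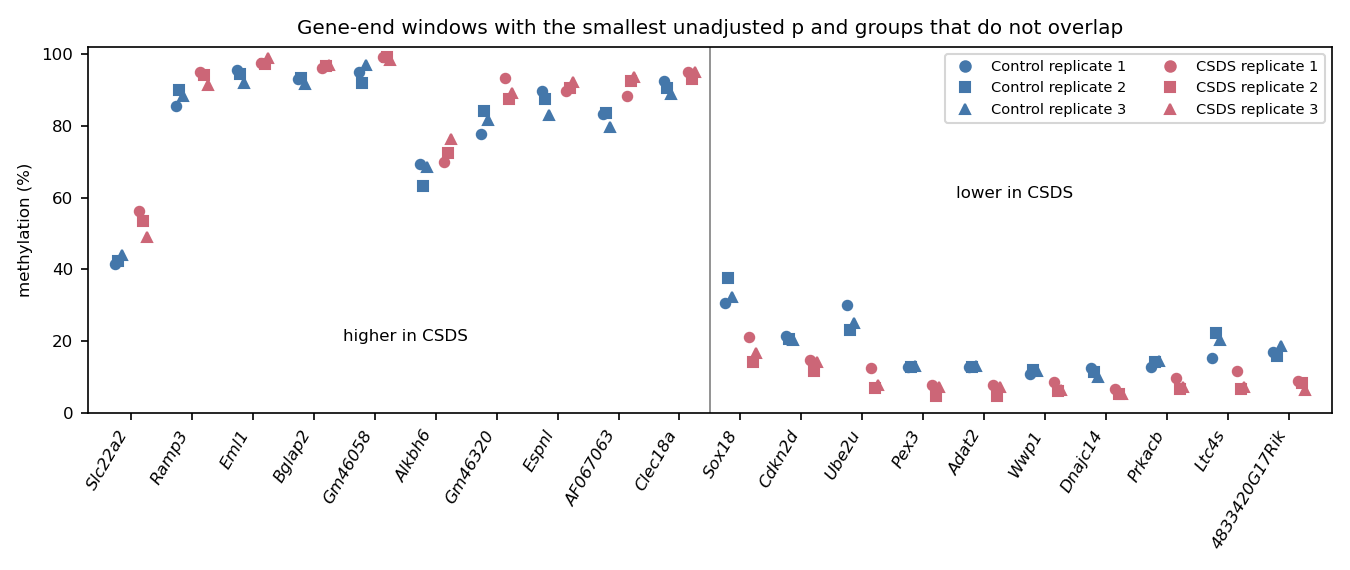
Methylation in percent of 20 gene-end windows, each symbol 1 library (3 Control, 3 CSDS), 10 with higher and 10 with lower values in CSDS. None passed the test; Sox18 has group means of 33.5% and 17.3%, Slc22a2 of 42.6% and 53.0%.

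Of 14690 gene-end windows, 0 were called at an adjusted p under 0.05 and 10 points by the quasi-binomial F test with limma's moderation, where 5721 had an unadjusted p under 0.05. The lowest adjusted p by this quasi-binomial F test with limma's moderation was 0.121, shared by each named lower window, Sox18, Ube2u and Ltc4s among them, and Slc22a2 had 0.126. Unadjusted, the p of this test was 0.000446 for Sox18, 0.000937 for Ube2u, 0.00138 for Ltc4s and 0.0451 for Slc22a2. limma on logit values called 90 windows and edgeR 64, all lower in CSDS. A term that sets CSDS replicates 2 and 3 apart from the other libraries leaves CSDS replicate 1 alone against Control. Its calls are those of 1 CSDS library and are not read as a group result. Without CSDS replicate 1 the CSDS group is just the 2 libraries with the low mitochondrial share, so group and share cannot be separated, and there the quasi-binomial test called 213 windows, 212 of them lower, among them Sox18 (−18.0 points), Ube2u (−18.7) and Ltc4s (−12.2). AF067063 was called higher there (+10.9 points). Every CSDS library was below every Control library at 5884 windows and above at 48, together 40.4%, where chance gives 10%. After the mitochondrial correction these were 1226 and 431, or 11.3%.

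Genes of the germ line are to be read against all windows, of which 94.8% were lower in CSDS and 62.7% after the mitochondrial correction. As deposited the list medians over genes differed by −3.77 points (germline-specific), −3.37 (spermatogenic stages) and −3.59 (DNA methylation and piRNA machinery). Maternal and paternal imprints differed by −3.65 and −3.41. After that correction the 5 differences were −0.725, −0.0477, −0.227, −0.453 and −0.417 points. Differences of single genes are as deposited unless said. Of 17 measured germline-specific genes 17 were lower, and 13 after correction. Examples are Tex19.1, which restrains transposons (39.3% ± 3.51 against 31.0% ± 4.82, −8.30 points), the piRNA helicase gene Mov10l1 (−7.29), the testis bromodomain gene Brdt (−6.38) and the ribosomal gene copy Rpl10l (−6.03). Of 12 genes of spermatogenic stages 12 were lower, 8 after correction, with Hspa1l (−10.1 points), Tnp1 (−5.02), Uchl1 (−4.43) and the protamine gene Prm1 (−3.86) the farthest apart. Prm1 stood at +0.122 points without CSDS replicate 2, Hspa1l at −4.98 without Control replicate 2, Mov10l1 at −2.36 without Control replicate 3 and Rpl10l at −3.98 without CSDS replicate 3. Of 10 genes of DNA methylation and piRNA machinery 9 were lower, 5 after correction. Zfp57, the zinc finger protein that protects imprints, had the largest difference of any listed gene, 72.5% ± 13.3 against 46.7% ± 11.2 (SD, n = 3 each, −25.8 points, −26.2 after correction), over only 3 cytosines with 43 to 176 reads. Uhrf1 (−4.87 points), Tet1 (−4.39) and Tdg (−4.33) followed. The 15 maternally imprinted genes included 14 lower and 13 after correction, led by Gnasas1 (−7.55 points), Grb10 (−5.28), Nnat (−5.11, −3.18 without CSDS replicate 2) and Airn (−5.10, −2.30 without Control replicate 2). The 3 paternally imprinted genes were lower, 2 after correction, at Rasgrf1 (−4.53 points), Meg3 (−3.36, −1.27 without CSDS replicate 2) and H19 (−0.969, +2.06 after correction). H19 was also above Control without Control replicate 1 (+0.560), Control replicate 2 (+0.415), CSDS replicate 1 (+0.9954) or CSDS replicate 3 (+0.3495). Without CSDS replicate 1, where only the libraries with the low mitochondrial share remain in CSDS, Tex19.1 (−10.6 points), Hspa1l (−15.2) and Zfp57 (−31.3) were called.

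Genes of the stress response and of behaviour are to be read against the same 94.8% of all windows lower (62.7% after correction). As deposited the list medians over genes differed by −3.58 points (stress axis), −3.18 (chromatin factors), −4.01 (neuronal genes) and −3.60 (metabolism). After the mitochondrial correction they differed by −0.205, +0.227, −0.736 and −0.304 points. The differences of single genes below are as deposited. Of 12 genes of the glucocorticoid and stress axis 12 were lower and 7 after correction, with Crh, the corticotropin-releasing hormone (12.3% ± 4.09 against 6.85% ± 2.33, −5.42 points), its pituitary target Pomc (−5.26), the glucocorticoid-induced kinase gene Sgk1 (−4.86) and Ucn (−4.32). Of 14 stress-responsive chromatin factors 14 were lower and 7 after correction, with Atf7 (−4.60 points), Cbx3 (−4.29), Hdac1 (−4.05) and the histone methyltransferase gene Ehmt2 (−3.76). Of 16 neuronal genes 16 were lower and 10 after correction, with Bdnf (−6.43 points), the serotonin receptor gene Htr1a (−5.27), the dopamine receptor gene Drd1 (−4.96) and Gad1 (−4.95). Of 14 metabolic genes 13 were lower and 10 after correction, with the leptin gene Lep (27.1% ± 4.60 against 19.04% ± 2.82, −8.09 points), Pck1 (−7.48), Pparg (−5.77) and Insr (−4.94). Single libraries carried part of some of these: Crh was at −3.06 points and Pck1 at −4.68 without Control replicates 3 and 2. Bdnf was at −4.02 without Control replicate 1 and Drd1 at −3.30 without CSDS replicate 2. The difference of Ehmt2 was larger without CSDS replicate 1, at −5.72 points.

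Markers of Sertoli and Leydig cells are few. Of 8 Sertoli cell genes 6 were lower, beside 94.8% of all windows, and 4 after correction, with Cldn11 at 25.3% ± 5.78 against 15.7% ± 3.61 (−9.58 points), Clu at −5.13, Dhh at −4.55 (−2.79 without Control replicate 2) and Wt1 at −4.13 (−2.56 without CSDS replicate 2). Of 4 Leydig cell genes 4 were lower before and after correction, with Insl3 at −9.51 points, Lhcgr at −3.59 (−1.84 without CSDS replicate 2), Star at −1.19 (−0.0505 without CSDS replicate 3) and Cyp11a1 at −0.965 (+0.0143 without CSDS replicate 1). The immune gene Adgre1 differed by +0.303 points. It turned to −0.234 without Control replicate 1, to −0.0968 without Control replicate 3 and to −0.415 without CSDS replicate 3. Cldn11 (−11.7 points) and Insl3 (−10.9) were called without CSDS replicate 1, again with only the low-share libraries in CSDS.

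In each of the 14 lists, with Hox genes and clustered protocadherins the last 2, 0 members were called over all windows and 0 adjusted over the list alone. In the Hox list 4 genes had an adjusted p under 0.05 over the list alone but differences under 10 points. Of its 37 measured genes 12 had an unadjusted p under 0.05 by the quasi-binomial F test, beside 38.9% of all windows. No list differed from the other windows by limma's camera, with a lowest adjusted p of 0.851 over 12 lists, that of the germline-specific genes, and 0.999 with an estimated correlation. The median log2 logit difference was negative in all 12 lists (−0.69 to −0.44). camera, which ranks a list against all other windows, gave the direction as up for 6 of them. By limma's fry, which asks only whether a list moves on balance, the lowest adjusted p was 0.138.

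Among 500-bp tiles of smallest unadjusted p with groups apart, Ube2u, Prpf4 and Zfp978 held lower methylation in CSDS and Trio, Slc38a7 and Pde11a higher, and none passed. The Ube2u tile (chromosome 4 from 100478501 to 100479000, 14 cytosines, 491 to 1045 reads) stood at 29.0% ± 3.75 in Control and 9.79% ± 2.54 in CSDS (SD, n = 3 each, −19.2 points, −17.5 after the mitochondrial correction). The splicing gene Prpf4 differed by −15.6 points (29.8% ± 1.49 against 14.2% ± 1.96, −13.7 corrected) and the zinc finger gene Zfp978 by −14.2 points (81.4% ± 1.28 against 67.1% ± 2.49, −14.3 corrected). Etv5, a transcription factor needed for renewal of spermatogonial stem cells, differed by −10.8 points (15.9% ± 0.786 against 5.08% ± 0.895, −8.10 corrected). Hif3a (−7.28 points), a tile shared by Abce1 and Anapc10 (−9.49), Prom1 (−7.52) and Zscan22 (−8.93) had corrected differences of −4.28, −6.74, −4.66 and −5.98 points. Tiles outside genes lay nearest to Ajap1 (−13.5 points) and Barx1 (−11.9). Higher tiles lay within Trio (37.6% ± 6.51 against 51.2% ± 2.49, +13.7 points), Slc38a7 (+11.8), Pde11a (+11.8, +7.73 without Control replicate 2), Slc22a2 (+11.7), Slc14a2 (+11.6), Add1 (+8.10), Reep3 (+4.35) and Ranbp10 (+3.67), and nearest to Tuba1a (+13.9) and Kcnh2 (+6.29).

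Of 162809 tiles, 0 were called by the quasi-binomial F test with limma's moderation, which gave 25447 an unadjusted p under 0.05 and a lowest adjusted p of 0.174. limma on logit values called 0 and edgeR 276, of which 15 were higher. With the term for CSDS replicates 2 and 3 the comparison is again that of CSDS replicate 1 alone against Control. With CSDS replicate 1 left out, so that group and mitochondrial share are the same contrast, the quasi-binomial test called 2406 tiles, 2370 of them lower, and among the tiles above those of Ube2u (−20.6 points), Prpf4 (−16.4), Zfp978 (−15.7), Etv5 (−11.3), Trio (+14.9), Slc38a7 (+10.6) and Pde11a (+11.7). Groups did not overlap at 26482 lower and 2959 higher tiles, 18.1% against the 10% that chance gives. After the mitochondrial correction the counts were 12144 and 5718, or 10.97%.

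Single cytosines of smallest unadjusted p were lower in CSDS within Mia2, Csf2ra, Ttll8, Pard6b, Sema6d and Ube2u and near Hoxc13, Tmem30b and Acvr1b, and higher within Arid3b, Rhpn2, Wnt5b, Rbm20, Phactr3 and Wwox and nearest to Pi4k2b, Ripk2, Adamts1 and Iftap. The Mia2 cytosine (chromosome 12 at 59131018, 52 to 100 reads) stood at 25.5% ± 15.4 in Control and at 0% in each CSDS library (−25.5 points). That is below the mitochondrial share, so its corrected CSDS mean was −6.21% and its corrected difference −24.1 points. On corrected counts its adjusted p was 0.412 by the quasi-binomial F test with limma's moderation. The cytosines of Csf2ra, Hoxc13, Sema6d, Acvr1b and Ube2u (at 100478894) were also at 0% in each CSDS library. The Ttll8 cytosine (chromosome 15 at 88891213, 32 to 61 reads) stood at 87.7% ± 4.99 and 41.1% ± 23.9 (−46.6 points), and the 2 neighbouring Ube2u cytosines differed by −25.3 and −29.8 points. The Arid3b cytosine (chromosome 9 at 57836271, 115 to 178 reads) was at 24.5% ± 8.97 and 47.9% ± 7.63 (+23.4 points), and that of Wnt5b (chromosome 6 at 119532344, 30 to 75 reads) at 79.5% ± 1.98 in Control and 100% in each CSDS library (+20.5 points). Of 2182877 tested cytosines, 0 were called by the quasi-binomial F test with limma's moderation, 236471 had an unadjusted p under 0.05, and the lowest adjusted p, at Mia2, was 0.0619. The Phactr3 cytosine (+13.7 points) stood at +7.11 without Control replicate 3. The Mia2 cytosine passed where the coverage minimum was 20 reads (adjusted p 0.0147 by the same test). With no upper limit on coverage the test called 492 cytosines, among them 14 of the 20 named here, such as Mia2, Ttll8, Arid3b, Wnt5b and both of Ube2u. Both cytosines of each CpG summed gave 106 calls, limma 0 and edgeR 4079. Groups did not overlap at 232093 lower and 38080 higher cytosines, 12.4% against 10% by chance, and at 119559 and 126614 after the mitochondrial correction.

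**Figure D4:**
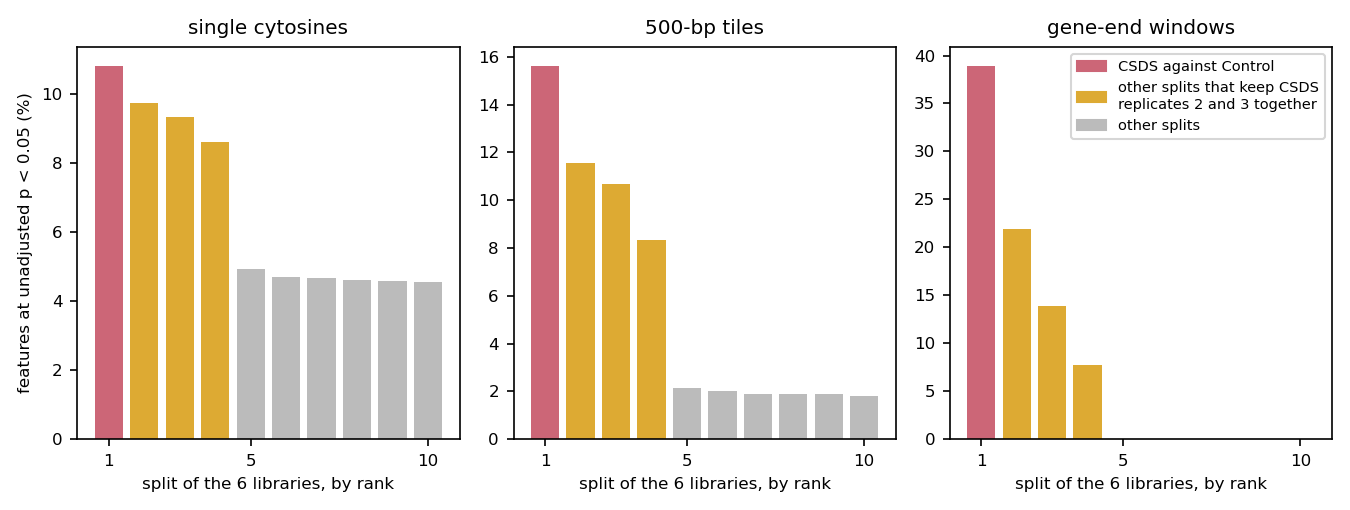
Percent of tests with an unadjusted p under 0.05 in each of the 10 divisions of the 6 libraries into 3 and 3. The real division gives 10.8% of cytosines, 15.6% of tiles and 38.9% of gene-end windows.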

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

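Settings tied to non-conversion or to strand-discordant CpGs, the other gene end, 2 kb windows, and CSDS replicate 1 alone against Control were chosen only after the results were seen; the rest were planned. The cause of a changed count was not tested unless said.

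For single cytosines 14 of 20 settings kept 0 calls, but some could call little: in simulated data the model with the conversion term called 0 of 200 changed cytosines, and limma at most 32% at any size. In each tally the settings with no difference minimum and with one of 25 points could not change a count of 0. The reason is that 0 features had an adjusted p under 0.05. CSDS replicate 1 alone is an arm of 1 library, and so is the group difference with the conversion class as a term. Fisher's exact test on summed counts, which by construction leaves out the spread between replicates, called 155658 cytosines, 2917 tiles and 113 gene-end windows. A coverage minimum of 20 called 1 cytosine, removal of strand-discordant CpGs 1, both cytosines of a CpG merged 106, no coverage cap 492 (108 of them above the cap) and edgeR 4079. For tiles 20 of 24 settings kept 0. edgeR called 276, and 257 with the conversion class as a term. For gene-end windows 18 of 23 settings kept 0. limma on logit values called 90, edgeR 64 and edgeR with the conversion class 15. In simulated data edgeR also called 109 unchanged tiles. Gene lists kept 0 in 11 of 11 settings, with lowest adjusted p between 0.138 and 0.999 by limma's set tests.

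Each replicate left out in turn gave 0 to 0 calls for cytosines, 0 to 2406 for tiles and 0 to 213 for gene ends, the highest without CSDS replicate 1, where group and mitochondrial share are the same contrast. The global difference ranged from −3.58 to −2.06 points, that of gene ends from −4.75 to −2.60, the maternal imprint median from −4.93 to −2.05 and the paternal from −2.82 to −1.97. The paternal median was −1.08 with a coverage minimum of 20 and −1.45 with reads summed. Ranges that cross 0 were those of the windows of Adgre1 (−0.415 to 1.24 points), H19 (−4.25 to 0.9954), Pcdhb12 (−14.1 to 0.974), Cyp11a1 (−1.47 to 0.0143) and Prm1 (−6.13 to 0.122), and of the imprint regions Peg10 (−0.0923 to 4.45), Peg3 (−5.08 to 0.975), Impact (−6.20 to 1.19) and Rasgrf1 (−1.79 to 0.280).

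The corrections turned some directions. By the mitochondrial share the maternal imprint median was +0.0265 points, the window of H19 +2.06 and the regions Gnas exon 1A, Peg3, Kcnq1ot1 and Impact +0.827, +0.918, +0.915 and +1.92, with Peg3 at −1.02 and Impact at −2.04 again without CSDS replicate 1. The corrected global difference ranged from −0.810 (without Control replicate 3) to −0.239 points. By the housekeeping share the maternal median was +0.365, gene ends +0.118 and CpG-dense DNA +0.325. The global difference kept its direction in 14 settings, from −4.43 (reads summed) to −0.236 points. Named genes and regions (133) kept their direction in 1127 of 1150 values. Windows, tiles and cytosines picked because their groups did not overlap cannot turn when a library is left out. Much of that tally is therefore fixed by the selection. In all, 38 values passed the threshold, 23 of them without CSDS replicate 1.

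With the replicate number as a block, 0 cytosines, 0 tiles and 0 windows were called, and the paired global difference was −2.60 points (exact sign-flip permutation p = 0.25, n = 3). The numbers do not pair the libraries: same-number correlations of tile deviations ran from −0.0490 to 0.00941, and 2 of 6 libraries correlated best with their own number. A coverage minimum of 5 and a window from 2 kb upstream to 500 bp downstream of the start could not give values. In simulated data 24% of 20-point changes were called at single cytosines, against 74% at gene ends.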

Other observations

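All tests of explanations below were chosen after the results were seen, and the pattern of intermediate cytosines was picked after several subsets of cytosines had been looked through; the count of other splits follows a fixed rule, with its outcome read after the counts were known.

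Hox genes and clustered protocadherins, both CpG-rich gene families, are set here beside all windows, of which 94.8% were lower in CSDS and 62.7% after the mitochondrial correction; the shares were not tested against each other. Of 37 measured Hox genes 35 were lower, and 24 after correction. Hoxc9 (16.02% ± 0.751 against 9.38% ± 2.15, SD, n = 3 each, −6.64 points), Hoxb8 (−6.36), Hoxb9 (−6.32) and Hoxd13 (−5.23) had an adjusted p under 0.05 over the list alone (0.034 for each by the quasi-binomial F test with limma's moderation), and Hoxb7 (−5.98) did not. None of them reached 10 points. By that test 12 of the 37 Hox genes had an unadjusted p under 0.05, beside 38.9% of all windows. Passing over the list alone therefore does not set these genes apart from other windows. After the mitochondrial correction 6 of the 37 had an unadjusted p under 0.05, beside 6.27% of all windows. The corrected differences of Hoxc9, Hoxb8, Hoxb9 and Hoxd13 were −3.66, −3.22, −3.22 and −2.03 points. Of 34 protocadherin genes 34 were lower, 29 after correction, with Pcdhga3 at −8.55 points (20.9% ± 8.73 against 12.3% ± 5.57), Pcdhga9 at −6.90, Pcdhb12 at −6.77 and Pcdhga4 at −5.65. Pcdhb12 turned to +0.974 points without Control replicate 1, Pcdhga4 stood at −3.12 without CSDS replicate 3 and Pcdhga3 at −4.82 without Control replicate 3, and Pcdhga3 was called at −11.8 points without CSDS replicate 1, where group and mitochondrial share are the same contrast. Neither family had a camera adjusted p under 0.05.

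The lower global level of the CSDS libraries (−2.60 points) came mostly with CSDS replicates 2 and 3. There 21 of 27 mitochondrial cytosines also lay lower than in each of the other 4 libraries, which argues against a nuclear methylation difference of the stress group as the whole cause. Incomplete bisulfite conversion that differs between libraries is a candidate explanation for most of it, but whether it explains all stays open. Corrected by the mitochondrial share the difference was −0.462 points, under the Control SD of 0.611. Without Control replicate 3, whose high mitochondrial share makes that SD, it was −0.810 with groups apart and a Control SD of 0.138. The housekeeping share of that library was the lowest in Control. The housekeeping share left −0.236 points with groups apart and a Control SD of 0.06005. That share is taken from nuclear gene ends and exceeds the mean at cytosines under 20% on average. The difference it leaves therefore does not settle whether non-conversion explains all. The labels name no library batch, the low share occurs in CSDS libraries only, and a stress difference of that size was not tested apart from it.

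At 58406 of 903591 CpGs with both cytosines measured (6.46%), the strands differed by 50 points or more the same way in all 6 libraries. The higher cytosine had a median of 97.6% and the lower 7.996%, with other cytosines near them at 6.65%, and the higher one was read less (median 20 to 29 reads per library against 62 to 79). Of 25126 neighbouring pairs of such CpGs, 84.3% had the higher cytosines on opposite strands, which argues against hemimethylation without a fixed order in the cells. The order reverse strand first, then forward, held in 62.4% of pairs (highest of 100 shuffles 25.5%), so methylated cytosine filled in at fragment ends is a candidate explanation. The global difference without these CpGs was −2.60 points, and no file gives fragment ends to test this further.

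Cytosines of intermediate methylation (20 to 80% on average, 248732) differed by more than the rest after the mitochondrial correction, at 43.3% ± 0.941 in Control and 40.3% ± 1.44 in CSDS (SD, n = 3 each, −3.00 points, exact permutation p = 0.1). That is over 2 Control SDs with groups apart. The subset was picked after several had been looked through, so this restates the pattern and does not test non-conversion at the mitochondrial rate alone. Where only 1 cytosine of a CpG was intermediate (66360) the difference was −6.21 points, and where both were (139942) it was −1.75. The gap was −4.46 points against a combined Control SD of 1.92, which treats the SDs of both sets as independent. These are separate sets of CpGs, and the partner cytosines of the first set were not compared. The gap therefore does not decide whether a group difference acts on both strands alike. A smaller share of filled-in ends in the CSDS libraries may explain the larger of these differences, but the gap does not decide that either. CSDS replicate 1 showed less (−2.96 and −0.663 points), and a stress difference at CpGs intermediate on both strands stays open and untested. Of the other cytosines, those at 80% or more on average differed by −0.711 points after the mitochondrial correction (Control SD 0.172, groups apart). Those under 20% differed by +0.236 points, with groups overlapping.

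The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division called 0 cytosines, 0 tiles, 0 gene ends and 0 lists, and the highest other division called 2, 0, 0 and 0. A count of 0 is reached by 10 of 10 by construction, so nothing follows from it. At an unadjusted p under 0.05 the real counts were 236471 cytosines, 25447 tiles and 5721 gene ends, and the highest of the others 213126, 18784 and 3221, so in each only 1 of 10, the real one, reached the real count. The 3 other divisions that keep CSDS replicates 2 and 3 together gave 8.32% to 11.5% of tiles and 7.75% to 21.9% of gene ends, while the 6 that part them gave 1.80% to 2.15% and 0.0204% to 0.0477%. After the mitochondrial correction the real division was not the highest for tiles (9836 against 11661) or gene ends (916 against 1913), and was the highest for cytosines (203394 against 194553).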
